A study of Homo sapiens with 6 samples.

How the data were processed

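Gene expression was measured in PC3 cells, an established human prostate cancer cell line, 72 hours after transfection with 60 nM of either an siRNA against JunD or a control siRNA. Per the labels' protocols, total RNA was extracted with Trizol, and biotinylated cRNA was prepared from 500 ng of total RNA. Each group had 3 arrays, which the labels call biological replicates, so p-values measure the spread between these samples. Groups and replicate numbers were taken from the sample labels.

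The deposited table held log2 expression values for 54675 probe sets on 6 arrays. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, which corrects background, quantile normalizes the arrays and summarizes the probes of each probe set. Their versions and settings are not given in the sources used here. That the values are on a log2 scale follows from their range in the deposited table, from 1.87 to 14.1, and from RMA's usual output. RMA compresses the differences of dim probe sets, so fold changes of weakly expressed genes can be understated. It also assumes that the distribution of values is alike on all arrays, so a change common to most genes would be removed. The table held 0 columns of other samples.

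Probe sets were named from the platform annotation, and symbols were checked by gene identifier against the RefSeq gene table of the GRCh38 assembly. Of the probe sets, 62 were controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 were not listed there. By gene identifier 41037 of the single-symbol probe sets matched, and 0 needed another symbol. Control probe sets and those without exactly 1 symbol were left out of the gene tests. For 10523 genes with over 1 probe set, the probe set with the highest mean over all 6 arrays was kept, without regard to group, which gave 19775 genes. Where probe sets of a gene named by the rule below differed in sign, this is given in the report.

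The single comparison was JunD siRNA minus control siRNA. It was tested per gene with limma 3.58.1 in R 4.3.3, using lmFit and eBayes at default settings, 2-sided, with Benjamini-Hochberg adjustment over all genes and an adjusted p threshold of 0.05. The model had 4 residual degrees of freedom and a prior of 3.35, and the median residual SD was 0.0858. Intervals of log2 changes are 95% confidence intervals. No filter on dim genes was applied. The number of arrays limits the precision. Single values per array were compared with 2-sided exact permutation tests, which cannot go below p = 0.1 with 3 arrays against 3.

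20 gene lists were fixed for the AP-1 family, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors, MYC targets, apoptosis, TGF-beta response with matrix and EMT, NF-kB and cytokines, interferon response, oxidative stress, the unfolded protein and amino acid stress response, cholesterol and fatty acid synthesis, hypoxia and glycolysis, core histones, housekeeping genes, ribosomal proteins, and markers of luminal prostate, stromal, leukocyte and neuroendocrine cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. The lists, tests, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. That rule took JUND and the AP-1 family, and then the 12 largest rises and falls past the threshold among genes of above-median level whose groups did not overlap. With fewer than 5 such genes in a direction, it took the 8 with the smallest p in that direction. From each list it took up to 4 members past the threshold or, with none, the 2 with the smallest p. Genes named outside it are said to be chosen after their values were seen.

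The gene test was checked on simulated arrays with the real genes' means and spreads, with 200 changed genes in each of 5 runs over 19775 genes. The changes were split equally between 1.2-, 1.5-, 2- and 3-fold, with noise independent between genes. The test recovered 19.6% of 1.2-fold changes, 73.6% of 1.5-fold changes and 96.4% of 2-fold changes, and 4.62% of its calls were false. With an intensity trend and robust variance, an alternative that called more genes in the real data, the same simulated arrays gave 25.6%, 78% and 97.6%, with 1.83% of calls false. Over all runs the default model made 757 calls and the alternative 766, against 5 and 292 in the real data. The real data held 16 genes at least 1.5-fold apart, fewer than each simulated run, so these rates may not carry over. With simulated uncorrelated noise, the list test called 25 of 25 lists shifted by -0.1 and 0 of 75 unshifted lists. Of the real lists, G1/S had an estimated correlation of 0.23, G2/M 0.43, interferon 0.80 and TGF-beta 0.003, against the preset 0.01. The check therefore does not cover the preset p-values of the more correlated lists.

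The alternatives were the replicate number as a block, leaving out dim genes, quantile normalizing again, shifting arrays to a common median or 75th percentile, averaging or separately testing a gene's probe sets, other variance models, array weights, other thresholds, and leaving out each array in turn. After the data were seen, a fit with each array's interquartile range as a covariate and a fit without array 3 of each group were added. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.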

Results

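JunD is a member of the AP-1 family of transcription factors. The design asked how its loss bears on genes of proliferation and cell cycle progression in PC3 cells, a human prostate cancer line that grows without androgen. RNA from 3 cultures given JunD siRNA and 3 given control siRNA was hybridized to 1 array each. Array medians lay between 5.24 and 5.29 on the log2 scale, and every pair of arrays correlated across all probe sets at r between 0.997 and 0.998.

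JUND mRNA was 3.53-fold lower with JunD siRNA. Its level was 10.61 ± 0.08 (log2, SD, n = 3) with control siRNA and 8.79 ± 0.05 with JunD siRNA, a change of -1.82 (SE 0.059, 95% confidence interval -1.96 to -1.68, limma adjusted p = 9.52e-05). The control arrays read 10.62, 10.52 and 10.67, and the JunD siRNA arrays 8.73, 8.82 and 8.82, so each array matched its label. Of the other JUND probe sets, all dimmer, 203751_x_at gave -0.75, 214326_x_at -0.74 and 229117_s_at -0.07. Averaging the 4 probe sets brought the change to -0.84.

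JUND was the 1 member of 14 measured AP-1 family genes that changed, over all genes and adjusted over the list alone. FOS, an early response gene that pairs with Jun proteins, differed by 0.29 (adjusted p = 0.449), FOSL2 by 0.14, ATF3 by 0.15 (-0.01 at another probe set), JUN by 0.10, FOSB by 0.10 and JUNB by 0.08. ATF2 differed by 0.05, MAFG by 0.04, FOSL1 by -0.02, MAFF by -0.04, BATF by -0.12, BATF3 by -0.12 and JDP2 by -0.12. The list's mean was -0.09, pulled down by JUND, while its median was 0.04 and camera's direction was upward without passing the test (adjusted p = 0.921).

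5 of 19775 genes changed at an adjusted p under 0.05, of which 2 rose and 3 fell. After JUND the largest fall was in PRDX3, a mitochondrial peroxidase that removes hydrogen peroxide, which was 2.20-fold lower. PRDX3 read 11.47 ± 0.06 in controls and 10.33 ± 0.01 with JunD siRNA (log2, SD, n = 3), a change of -1.14 (SE 0.049, adjusted p = 4.02e-04). Its other, dim probe set gave -0.17, and the mean of both gave -0.65. SERPINB4, a serpin of squamous epithelia, rose 1.86-fold, by 0.89 (SE 0.068, adjusted p = 0.0144). Its transcript is nearly identical to that of SERPINB3, and a probe set annotated to both gave 0.72, so which of the pair rose is uncertain. CTH, the cystathionine gamma-lyase that makes cysteine, rose 1.59-fold, by 0.67 (SE 0.054, adjusted p = 0.0184), and its other probe set gave 0.65. CMTM7, a membrane protein of the CKLF-like family, fell by 0.47 (SE 0.046, adjusted p = 0.0454), with -0.19 at its other probe set. Each of these 5 genes had all 3 JunD siRNA arrays on one side of all 3 control arrays.

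**Figure D1:**
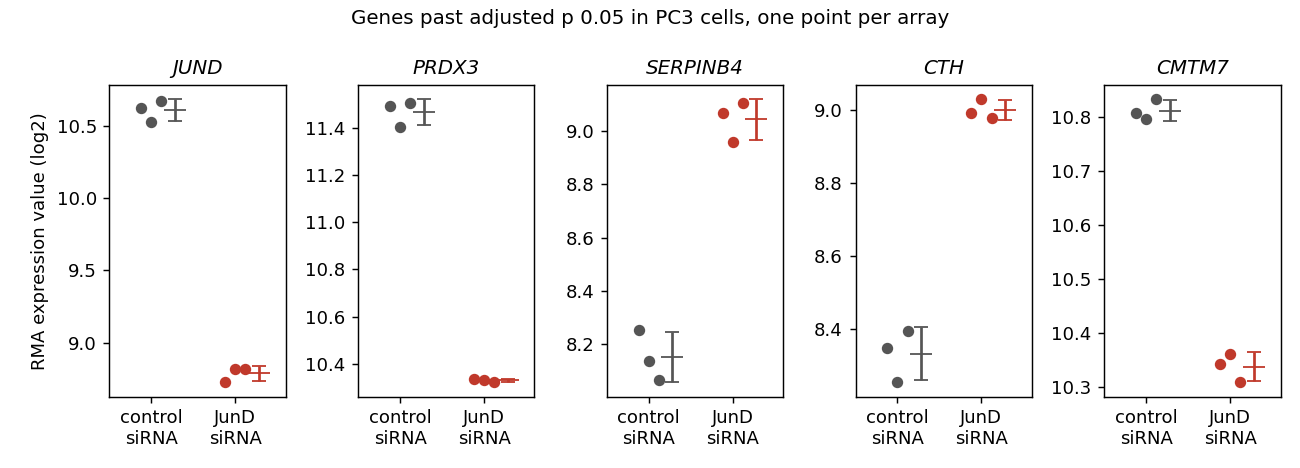
Log2 RMA expression of the 5 genes past an adjusted p of 0.05, with 1 point per array and a bar for the group mean ± SD of 3 arrays. The vertical axes differ between genes and do not start at 0; JUND and PRDX3 show the widest gaps, -1.82 and -1.14.

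The other genes with the smallest p in each direction did not pass the threshold with the default variance model, and all 11 passed with an intensity trend and robust variance or without the lower 50% of genes by level. None of the 11 passed in limma with the array interquartile range as a covariate (adjusted p from 0.117 to 0.205). Among those with higher values were KDM2A, a histone demethylase gene (0.63, adjusted p = 0.0537), PTGS2, which encodes cyclooxygenase 2 (0.67), TSPAN1 (0.55), MESD (0.51), RESF1 (0.51) and C1RL (0.46). The other KDM2A probe sets gave 0.13 and 0.16, and that of C1RL gave -0.04, while that of PTGS2 gave 0.77. Of the 5 MESD probe sets the dimmest gave -0.08 and another -0.05. Lower values were found for CCNA1, a cyclin A gene (-0.58), SRD5A1, a steroid 5-alpha-reductase (-0.42, adjusted p = 0.0776), ESM1 (-0.36), SENP5 (-0.33, with 0.04 at another probe set) and TFF2 (-0.32). Of all genes, 97.9% lay within 1.2-fold. At an unadjusted p under 0.05 there were 1929 genes where chance gives 989 for independent genes and other divisions of the 6 arrays gave 484 to 3424, and in 16.1% of genes the groups did not overlap where chance gives 10%.

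The count of changed genes depended on the variance model: an eBayes prior with an intensity trend gave 275 genes, and 292 when also robust, of which 212 rose. JUND and PRDX3 passed whichever 1 array was left out, SERPINB4 only without control array 1 or JunD siRNA array 2, and CTH and CMTM7 in none of these fits, which called 3, 2 and 2 genes without control arrays 1, 2 and 3 and 2, 3 and 2 without JunD siRNA arrays 1, 2 and 3. The changes themselves moved little in these fits, from 0.85 to 0.95 for SERPINB4, 0.63 to 0.70 for CTH and -0.49 to -0.46 for CMTM7.

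Genes of the cell cycle were slightly lower as groups with JunD siRNA. All 44 measured genes of G2/M and mitosis had lower means, with a median of -0.10 and a range from -0.29 to -0.01 (camera adjusted p = 7.25e-11 with the preset correlation; adjusted p = 0.428 with an estimated correlation). None passed over all genes by limma, 11 were lower at an unadjusted p under 0.05, and 3 fell when adjusted over the list alone: HMMR, a spindle-binding protein (-0.28), CDCA3, a trigger of mitotic entry (-0.25), and KIF2C, a kinesin that depolymerizes microtubules (-0.29), the last named after its value was seen. All 44 confidence intervals lay within 1.5-fold. The mean over the list was 9.62 ± 0.03 in controls and 9.51 ± 0.05 with JunD siRNA (log2, SD, n = 3; exact permutation p = 0.1, the smallest possible).

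Of 40 measured genes of G1/S and DNA replication, 37 had lower means, with a median of -0.08 (camera adjusted p = 2.36e-07; adjusted p = 0.415 with an estimated correlation). None passed over all genes by limma or adjusted over the list alone, and 9 were lower at an unadjusted p under 0.05. CDK2, the kinase of S phase entry, differed by -0.22 (adjusted p = 0.245) and E2F1, a transcription factor of the same step, by -0.19. Without array 3 of both groups the G1/S list lost its call, with a median of -0.05 (adjusted p = 0.0606, in a range from 3.30e-10 to 0.415 over the alternatives), and the G2/M and mitosis median was -0.05 (adjusted p = 0.0124, in a range from 2.26e-14 to 0.428). With an intensity trend and robust variance, 3 G1/S genes and 4 G2/M genes passed over all genes, all lower.

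CDK inhibitors and growth arrest genes were not called as a list (median 0.01, adjusted p = 0.126). Of 21 measured, 0 passed over all genes, with 4 higher and 1 lower at an unadjusted p under 0.05, and 2 rose when adjusted over the list alone: CDKN1C (0.21, with -0.18 at its dimmest probe set) and BTG1, an antiproliferative gene (0.21), which also passed over all genes with an intensity trend and robust variance. MYC and its targets had a median of -0.05 (adjusted p = 0.16), with 0.34 for MXD1, a MYC antagonist, and 0.20 for NOLC1, both of which passed with that variance model. Apoptosis regulators had a median of 0.00 (adjusted p = 0.724), with 0.21 for BIK and 0.16 for BID.

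**Figure D2:**
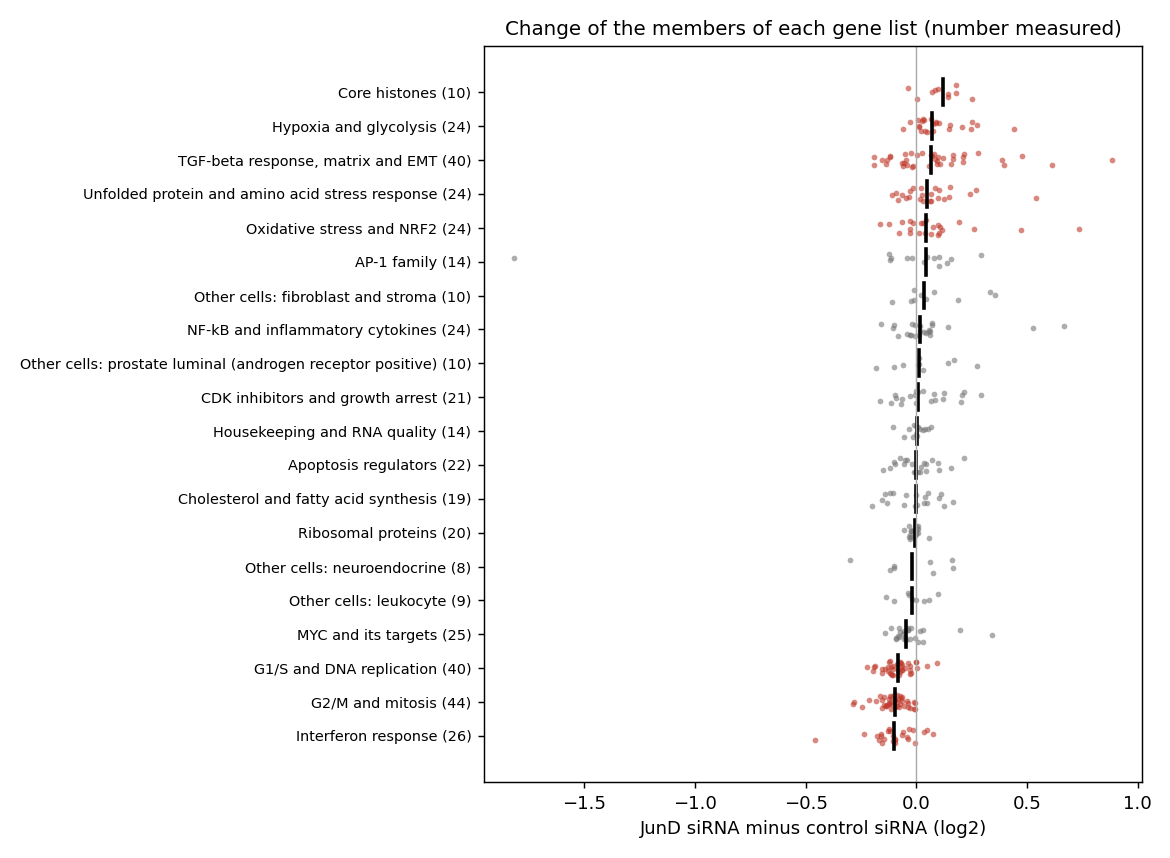
Log2 change, JunD siRNA minus control siRNA, of each measured member of the 20 gene lists, with 1 point per gene, a black bar at the list's median and the number of genes in brackets. Red lists passed camera with the preset correlation, 8 of 20, and none passed with an estimated correlation; the lone point at -1.82 is JUND.

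Genes of the TGF-beta response, matrix and EMT were higher as a group, with a median of 0.07 over 40 genes, 24 positive and 16 negative (camera adjusted p = 6.56e-04; adjusted p = 0.272 with an estimated correlation). This was the 1 list that passed fry (adjusted p = 0.014). None of its members passed over all genes by limma. At an unadjusted p under 0.05, 11 were higher and 3 lower: CCN2 (-0.19), SMAD3 (-0.15) and ZEB1 (-0.12), named after their values were seen. Adjusted over the list alone, 7 rose. These were MMP13, a collagenase (0.61), SMAD7, an inhibitor of TGF-beta signalling (0.39), and, named after their values were seen, CDH1, MMP3, MMP10, LOX and COL4A1. SMAD7 and LOX were dim, at 5.16 and 4.79 in controls. CDH1, which encodes the epithelial adhesion molecule E-cadherin, was 0.89 higher (SE 0.152, adjusted p = 0.169), opposite to its loss in EMT. Since CDH1 counts towards the rise, the list's direction cannot be read as EMT. Members of the TGF-beta response went both ways, with 0.39 for SMAD7, 0.09 for SKIL and 0.07 for THBS1. CCN2, SMAD3, TGFBI (-0.14), ID3 (-0.13), CCN1 (-0.06), ID1 (-0.05) and ID2 (-0.05) had lower values. All of these but SMAD7 were picked after their values were seen. The list's direction therefore cannot be read as a TGF-beta response either. Among genes picked after their values were seen, FN1 (0.15), TWIST1 (0.10), VIM (0.07), SNAI2 (-0.02), CDH2 (-0.04), SNAI1 (-0.05), ZEB1 (-0.12) and the dim ZEB2 (-0.19) did not pass adjusted over the list alone. With an intensity trend and robust variance 5 members of the list passed over all genes, all higher: CDH1, LOX, MMP13, SMAD7 and TIMP1.

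Hypoxia and glycolysis genes had a median of 0.07, with 22 of 24 positive (adjusted p = 1.27e-05; adjusted p = 0.415 with an estimated correlation). Adjusted over the list alone 4 rose, among them NDRG1 (0.27) and VEGFA, an angiogenic factor (0.25); 4 members also stand in other lists, NDRG1 among the luminal markers. Unfolded protein and amino acid stress genes had a median of 0.05, with 16 of 24 positive (adjusted p = 0.00546; adjusted p = 0.428 with an estimated correlation), and 3 rose when adjusted over the list alone, including DDIT4, an inhibitor of mTOR signalling (0.54), and HERPUD1 (0.24, with 0.00 at a dim probe set). Oxidative stress genes had a median of 0.04, with 16 of 24 positive (adjusted p = 0.0109, and adjusted p = 0.428 with an estimated correlation), and 2 rose when adjusted over the list alone, AKR1C1 (0.74, with -0.10 at a dim probe set) and AKR1B10 (0.47), which are aldo-keto reductases. AKR1B10 was dim, at 5.15 in controls. Core histones had a median of 0.12, with 9 of 10 positive (adjusted p = 1.24e-04, and adjusted p = 0.415 with an estimated correlation), and 1 of 10 rose when adjusted over the list alone, H2BC21 (0.25), beside 0.18 for H2BC5. The histone list also holds the linker histone H1-2 (0.08, named after its value was seen). None of the members of these 4 lists passed over all genes by limma, where 7, 5, 5 and 5 were higher at an unadjusted p under 0.05. At that threshold 1 member was lower, OSGIN1 of the oxidative stress list (-0.13), named after its value was seen. PRDX3 was not a member of the oxidative stress list. With an intensity trend and robust variance, 2 hypoxia genes (NDRG1 and VEGFA), 4 unfolded protein genes (DDIT4, DNAJB9, HERPUD1 and HSPA5), 1 oxidative stress gene (ME1) and 1 histone gene (H2BC21) passed, all higher; those outside the rule for names were named after their values were seen.

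Interferon response genes had a median of -0.10 over 26 genes, 23 of them negative (adjusted p = 0.00546; adjusted p = 0.779 with an estimated correlation), with -0.18 for IRF7 and -0.46 for the dim IFNB1. No member passed over all genes by limma or adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. The NF-kB and cytokine list was not called (median 0.02, adjusted p = 0.225), although 2 members, PTGS2 (0.67) and IL1A (0.53, with 0.06 at its other probe set), rose when adjusted over the list alone. IL1A was dim, at 5.10 in controls. With an intensity trend and robust variance both PTGS2 and IL1A passed over all genes as higher and LIF as lower. Cholesterol and fatty acid synthesis was not called either (median 0.00, adjusted p = 0.838), with -0.20 for SQLE, which passed with that variance model, and -0.14 for FASN.

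The interferon call was lost without control array 2 (median -0.02, adjusted p = 0.484), control array 3 (-0.11, 0.0621) or JunD siRNA array 2 (-0.03, 0.354), its median was -0.20 without control array 1, and its adjusted p ran from 1.70e-08 to 0.779 over the alternatives. The unfolded protein list lost its call with the interquartile range as a covariate (median 0.04, adjusted p = 0.0746), without the lower 50% of genes by level (0.06, 0.0515) or without control array 1 (0.05, 0.0684), in a range from 0.00125 to 0.428, and its median was 0.03 without JunD siRNA array 1. The oxidative stress list lost its call with that covariate (median 0.03, adjusted p = 0.0824) or without JunD siRNA array 2 (0.03, 0.0511), in a range from 0.00359 to 0.428, with medians of 0.02 and 0.07 without control arrays 2 and 3. The hypoxia list kept its call with a median of 0.04 without control array 1 or JunD siRNA array 1. Without JunD siRNA array 1 the MYC (median -0.06, adjusted p = 0.047) and NF-kB (0.03, 0.0137) lists passed. The MYC list also passed without the lower 50% of genes (-0.04, 0.0414).

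Markers of other cell types did not pass as lists. Stromal markers had a median of 0.03 (adjusted p = 0.0668), with 0.36 for COL1A1 and 0.33 for LUM, a gene near the bottom of the scale at 2.62 in controls; both rose when adjusted over the list alone. The other COL1A1 probe sets gave 0.20, 0.20, 0.01 and -0.01, and that of LUM gave -0.10. COL1A1 also passed over all genes with an intensity trend and robust variance. In 5 of 21 alternatives this list passed, among them further quantile normalization (adjusted p = 0.0332), a common 75th percentile (0.0368) and leaving out JunD siRNA array 1 (0.047) or 2 (0.018), in a range up to 0.537. The stromal median was 0.01 without JunD siRNA array 1 and 0.08 without JunD siRNA array 2. Luminal prostate markers had a median of 0.01 (adjusted p = 0.441), with -0.18 for KLK2 and NDRG1 as the 1 member that rose adjusted over the list alone or over all genes with that variance model. Leukocyte markers had a median of -0.02 (adjusted p = 0.921), with -0.14 for LAPTM5 and -0.10 for PTPRC (0.03 at another probe set). Neuroendocrine markers had a median of -0.02 (adjusted p = 0.724), with 0.16 for INSM1 and -0.30 for CHGB, which fell adjusted over the list alone at a control level of 3.35.

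Housekeeping genes had a median of 0.00 (adjusted p = 0.921), with -0.11 for GUSB and 0.07 for PGK1 (-0.01 at another probe set), and ribosomal protein genes a median of -0.01 (adjusted p = 0.724), with -0.06 for RPS19 and -0.03 for RPL19. The difference between 3' and 5' GAPDH control probe sets, a sign of RNA quality, was -0.07 ± 0.03 in controls and -0.09 ± 0.01 with JunD siRNA (log2, SD, n = 3, exact permutation p = 0.6), and that of ACTB was 0.26 ± 0.03 and 0.28 ± 0.05 (exact permutation p = 0.7). Spike-in controls read higher with JunD siRNA, by 0.11 for poly-A and 0.12 for hybridization spike-ins (exact permutation p = 0.2 for each). Both differences are of the size of the called lists' median changes. The first principal component held 37.5% of the variance and placed control array 3 (5.47) with JunD siRNA arrays 1 (6.28) and 2 (13.02), and JunD siRNA array 3 (-3.48) towards control arrays 1 (-10.59) and 2 (-10.70). The interquartile range of values was likewise narrower on control arrays 1 (3.63) and 2 (3.65) and JunD siRNA array 3 (3.66) than on control array 3 (3.78) and JunD siRNA arrays 1 (3.76) and 2 (3.78).

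**Figure D3:**
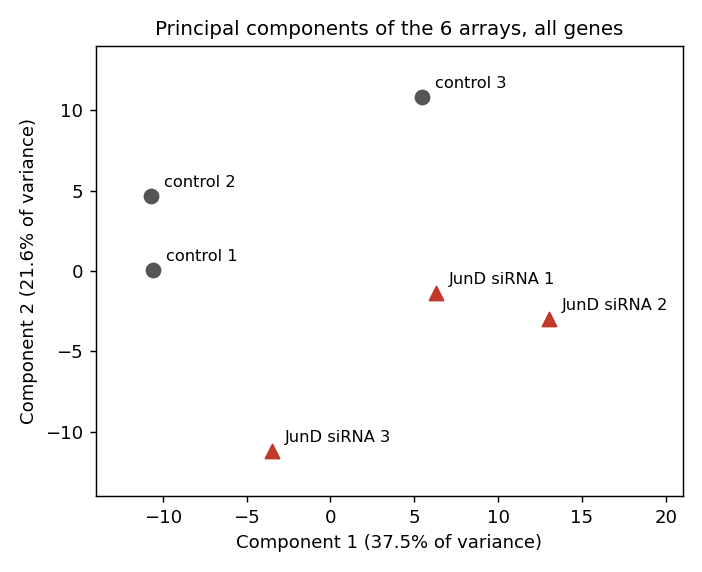
First and second principal components (unitless scores) of the 6 arrays over all genes, with control arrays as grey circles and JunD siRNA arrays as red triangles. Component 1 places control array 3 at 5.47, beside JunD siRNA array 1 at 6.28.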

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

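Of the tests in this part, those of the counts of genes, of PRDX3 and of the array order were chosen after the results were seen. The added covariate and the fit without array 3 of each group were also chosen then. The tests of the gene lists were written before the values of those tests were seen, though the G2/M test of array spread uses that covariate. Among probe sets left out of the gene table, 213598_at, which the annotation used here does not list, stood out because it passed the same test outside the gene table. It fell by 0.857 on the log2 scale (SE 0.071, adjusted p = 0.0207 over 54613 probe sets). The 6 arrays can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real division called 5 genes and the highest other 0 (1 of 10 as large), 4 genes of at least 1.5-fold against 0 (1 of 10), 292 genes with an intensity trend and robust variance against 0 (1 of 10), and 8 gene lists against 5 (1 of 10).

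The small joint decrease of the G2/M genes could come from the spread of values on each array or from a single array. With the interquartile range as a covariate the list mean changed by -0.129 (SE 0.028) against -0.108 without it, which argues against that spread as the whole source. The highest of 6 leave-one-out medians was -0.078, which argues against 1 array deciding it, while without array 3 of both groups the median was -0.054. In other divisions the absolute median reached 0.093 against 0.099 (1 of 10 as large). That of the G1/S list reached 0.077 against 0.081. An effect of JunD loss on cycling, an off-target action of the siRNA, or a difference in density or growth between wells stays open as a hypothesis. No cell counts were analysed here. The single comparison cannot tell an effect of JunD loss from an off-target action, here or for the other genes and lists.

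PRDX3 fell more than any other gene after JUND. An artifact of its probe set might be read from the other PRDX3 probe set, at -0.166, but that one is dimmer than the median gene and cannot decide. The other 4 measured peroxiredoxin genes had a median change of 0.041 (SD 0.053), which argues against a joint decrease of the family. Regulation by JunD may give this fall, and so may an off-target action of the siRNA, which was not tested because its sequence is not given in the sources used here.

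The arrays also parted as control arrays 1 and 2 with JunD siRNA array 3 against the rest. That division gave 3424 genes at an unadjusted p under 0.05 against 1929 for the real one (2 of 10 as large), which points to a structure of the samples apart from the siRNA. JUND of control array 3 lay 1.85 above the highest JunD siRNA array, which argues against a swap of arrays 3. Of the genes of that division 70.4% were dimmer than the median gene, but the other 8 divisions apart from the real one gave 61.6% to 94.4%, so this says nothing particular about it. The spread of the arrays' values stays open as a source, and no batch label was found.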

How the results depend on the processing

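The fit with the interquartile range and the fit without array 3 of each group were chosen after seeing the data. JUND stayed called in 19 of 19 alternatives (-1.86 to -0.84, adjusted p from 7.56e-12 to 0.0195) and PRDX3 in 18 (to 0.0618, without array 3 of each group), SERPINB4 in 12, CTH in 10 and CMTM7 in 8. Against 5 changed genes (2 up, 3 down) there were 28 without the lower 25% of genes by level (24 up, 4 down). Without the lower 50% there were 133 (96 up, 37 down). Fewer genes were tested there, and the variance prior was estimated anew. With 50% of the tests an adjusted p can at most halve, and 28 genes had one under 0.10 in the main fit. Fewer tests alone therefore cannot give 133. Quantile normalizing again gave 10 (6 up, 4 down), a common median 23 (20 up, 3 down), a common 75th percentile 4 (1 up, 3 down), an intensity trend 275 (203 up, 72 down), a robust trend 292 (212 up, 80 down) and array weights 13. The interquartile range as a covariate gave 3, leaving out array 3 of each group 1 and single arrays 2 to 3, with fewer samples. Thresholds of adjusted p 0.01, adjusted p 0.10 and unadjusted p 0.05 gave 2, 28 and 1929. Against 4 genes of at least 1.5-fold there were 8 without the lower 25%, 12 without the lower 50%, 9 with a common median, 15 with a trend, 14 with a robust trend, 1 without array 3 of each group, 2 to 3 without single arrays, 2 at 2-fold and 2 with treat. The same replicate numbers did not pair arrays (deviations correlated at -0.16, -0.29 and -0.41, and no array best with its own number), and the replicate block gave 2 genes, and 2 of at least 1.5-fold, and called the stromal list (adjusted p = 0.0492, in a range from 0.018 to 0.537). Against 8 gene lists, an estimated correlation gave 0 and fry 1. The G1/S and G2/M medians of -0.081 and -0.099 lost their calls with an estimated correlation (adjusted p = 0.415 and 0.428) and fry (0.0968 for both), and G1/S also without array 3 of each group (-0.049). Of named genes under single alternatives, 104 values became called and 30 lost the call. The rest kept their side of the threshold. Of these, 31 stayed uncalled but moved by more than 1 SE of the main fit. The other 1055 stayed called, or stayed uncalled within 1 SE. Of gene lists 403 kept their side, 8 gained a call and 24 lost it. How far the gene sets, the variance priors and the sample numbers each caused these differences was not tested. Low signal over background limits dim genes.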

Other observations

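The genes in this part, AKR1C1 excepted, were chosen after their values were seen, and none of those given a value here passed over all genes by limma with the default variance model. Of 16 genes at least 1.5-fold apart, 14 were higher with JunD siRNA, and 4 of the 16 passed. The 4 measured aldo-keto reductase 1C genes, which reduce steroids and other carbonyls, had a median of 0.56. The changes were 0.81 for AKR1C2 (SE 0.099, adjusted p = 0.0745), 0.74 for AKR1C1, 0.39 for AKR1C3 and 0.15 for AKR1C4, which read 2.83 in controls. These genes share much sequence, so single members are uncertain. The 11 SERPINB genes had a median of 0.10, with 9 positive and 4 higher at an unadjusted p under 0.05. SERPINB3 differed by 0.54, SERPINB7 by 0.34 and SERPINB5 by 0.30, against 0.06 for SERPINB12, 0.02 for SERPINB9, 0.00 for SERPINB8, -0.03 for SERPINB10 and -0.06 for SERPINB11. CP, the copper-carrying ceruloplasmin, was 1.90-fold higher (0.92, SE 0.152, adjusted p = 0.16), and its other probe sets gave 0.87, 0.78 and 0.66. CYP1B1, a cytochrome P450 of the xenobiotic response, differed by 0.64 (adjusted p = 0.0745), ARL14 by 0.71, BMP2 by 0.63 and CLIC3 by 0.63. CYP1B1 and BMP2 were dim, at 4.67 and 5.34 in controls. With an intensity trend and robust variance AKR1C2 (adjusted p = 0.00542), AKR1C3 (0.0187), SERPINB3, SERPINB5 (0.0154) and SERPINB7 passed. CP (0.0152), CDH1 (0.00426), CYP1B1 (0.00435), ARL14 (0.00407), CLIC3 (0.0123) and BMP2 (0.0196) passed as well. AKR1C1 (0.0506), AKR1C4 (0.545) and the remaining SERPINB genes given a value here did not.

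CCND1, MYC, CDK1, PCNA, MKI67 and CDKN1A, picked after their values were seen, did not pass adjusted over all genes. CCND1 differed by -0.03 (95% confidence interval -0.14 to 0.08), MYC by -0.04 (-0.17 to 0.10), CDK1 by -0.08 (-0.21 to 0.06), PCNA by -0.06 (-0.17 to 0.04), MKI67 by -0.07 (-0.18 to 0.05) and CDKN1A by 0.09 (-0.06 to 0.23).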
